A study of Mus musculus with 12 samples.

How the data were processed

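RNA-seq of 12 mouse libraries was analysed from 1 deposited table of raw counts per Ensembl gene, with 1 column per sample and 3 libraries in each of 4 groups. Per the labels, wild-type primary cells were isolated from intestinal muscle layers and kept for 28 days in P medium on a well plate, in M medium on a well plate or in M medium on an electrospun gelatin scaffold, and muscle strips were the positive control. The labels of the strips also carry the 28-day time point and the source name of the cultured cells. The title and the design text call them muscle strips, and they were treated as such. Total RNA was isolated with Qiashredder and RNeasy kits, and libraries were made with the TruSeq RNA Library Prep Kit v2. The processing notes of the labels name STAR 2.6.0 and the genome builds GRCm38 and mm10. The deposited values are counts: whole numbers, with library totals that differ between samples. The 5 summary entries at the end of the table have the names that htseq-count writes, but the counting program, the gene annotation, the strand setting and the read layout are not given in the sources used here. The series text speaks of 2 technical replicates per sample, while the table holds 1 column per sample, and how the runs were joined is not given in the sources used here.

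The table held 52550 genes, of which 52403 were matched by Ensembl identifier to a symbol in GENCODE M21, which also gave the GRCm38 coordinates. The 5 summary entries were left out of library sizes and tests. They served for the shares of reads outside annotated features, which were 4.20% to 5.89% in P plate, 5.73% to 6.44% in M plate, 4.48% to 5.12% in M scaffold and 6.82% to 7.87% in strips. The most abundant gene took at most 3.28% of the counts of any library. No library was left out. Counts between replicates differed from each other by far more than sampling error (chi-square per gene of 40.7 to 446), so no column is another read of the same library. A second library from the same RNA is not excluded, since it could also differ by more than sampling error.

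Gene counts per library ranged from 21396485 to 116643512. A count of 0 allows up to 3 counts, which is 0.0271 to 0.125 CPM across the libraries. For genes with no counts in a group, the floor of 3 counts was taken over the group. Floors cover counting error only, since reads without molecular identifiers are not independent molecules. CPM values are scaled by TMM factors, which ranged from 0.893 to 1.15, and are given as mean ± SD of 3 libraries.

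Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, which left 17700, and scaled by TMM. A quasi-likelihood negative binomial model was fitted to all 12 libraries with the group as the only term, which leaves 8 residual degrees of freedom. Each of 5 comparisons was tested with the quasi-likelihood F test. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The standard error of a log2 fold change was taken from the F statistic. All adjusted p values of genes are two-sided, over 17700 genes within a comparison.

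The 27 gene lists cover cell types of the gut muscle wall (smooth muscle contractile apparatus, smooth muscle excitation and signalling, interstitial cells of Cajal, enteric neurons, enteric glia, fibroblasts, pericytes and vascular mural cells, mesothelium, endothelium, macrophages and myeloid cells, lymphocytes, intestinal epithelium, adipocytes) and processes (cell cycle, extracellular matrix, matrix proteases and inhibitors, Wnt, BMP, YAP and TGF-beta target genes, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, inflammatory mediators, interferon response, immediate early and handling stress, p53 response and cell cycle arrest). Each was tested with camera from limma 3.58.1 at the preset correlation of 0.01, which compares a list with the other genes, and adjusted over the 27 lists of a comparison. Alternatives were camera with an estimated correlation, which only the matrix protease list passed, in the 3 comparisons with strips, and fry, which tests a list without reference to other genes. Counts adjusted over the list alone apply the Benjamini-Hochberg method to the p values of the members of that list. Members that did not pass the low-count filter were not tested.

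The groups, the comparisons, the test, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. For each comparison the rule took the 5 largest rises and the 5 largest falls among called genes with a mean of at least 20 CPM in the higher group and no overlap between the libraries of the groups, leaving out predicted genes and mitochondrial genes. From each list it took up to 3 called members in the main direction and 1 in the other. It also took a panel of 16 markers, among them Acta2, Myh11, Tagln, Des, Actg2, Kit, Ano1, Pdgfra, Tubb3, Elavl4, Gfap, S100b, Mki67, Pecam1 and Ptprc. The text names a part of these genes, and some that the rule took are not reported here. Lyz2, Cd68, Msln, Slc2a1, Kit and Lyve1 are also given per library where a library stood apart, and these uses were chosen after the values were seen.

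Whether replicate numbers pair the groups was checked by correlating, across genes, the residuals of same-numbered libraries of the compared groups. A correlation above 0.1 in all 3 pairs was taken as pairing, which held for M scaffold against M plate only, and the value with the replicate number as a block is given there. Lower correlations do not exclude pairing in the other comparisons, since replicate 2 had the lowest ratio of Y-linked to Xist counts in every group.

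Alternatives were DESeq2 size factors or library totals in place of TMM, no low-count filter or at least 1 CPM in 3 libraries, the Wald test of DESeq2 1.42.0, limma-voom, the 6 compared libraries alone, the replicate number as a block, a minimum fold of 2 with glmTreat, leaving out mitochondrial genes, and leaving out each library in turn. The Wald test came with the size factors of DESeq2 and 17623 tested genes, and the low-count filter was run anew wherever libraries or genes were left out. Added after the data were seen were the block within the 6 compared libraries, thinning of all libraries to the smallest total, leaving out P plate replicate 1, M scaffold replicate 3 and strips replicate 2 together, and list tests within the 6 libraries and with library totals. The pipeline was tested on simulated data with the means and spreads of these libraries. The first group of a comparison was given the means of the second before genes were changed. Genes were drawn independently, so correlation between genes and libraries that stand apart were not covered. Of 100 genes changed 2-fold, 41 were called in M plate against P plate and 41 in M scaffold against M plate. Of 100 changed 4-fold, 89 and 81 were called. The changed genes were drawn from those above a set read level, so recovery of genes read less was not covered. False calls among the 17700 genes were 4 of 134 calls and 15 of 137, the latter a larger share than the threshold of 0.05. For each comparison of groups the number of called genes was also counted in the other splits of its 6 libraries into groups of 3.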

Results

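RNA was sequenced from 12 mouse libraries in 4 groups of 3 biologically independent replicates. Primary cells from the muscle layers of the intestine were kept for 28 days in culture before RNA was taken. The P plate group grew on well plates in serum medium with 10% FBS, which the labels call proliferation medium. The M plate group grew on well plates in serum-free medium with N2, B27, the BMP antagonist Noggin at 100 ng/ml, the Wnt agonist R-spondin1 at 1 µg/ml and Y27632 at 10 µM, called differentiation medium. The M scaffold group had the same medium on an electrospun gelatin scaffold. Strips of intestinal muscle served as positive control. The counts assigned to genes came to 40935111, 32784531 and 33580793 in P plate replicates 1 to 3, and to 35684422, 40768812 and 65356837 in M plate. They came to 32477783, 34273262 and 116643512 in M scaffold, and to 31678057, 21396485 and 76361847 in strips.

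On the first principal component, which held 59.3% of the variance of log2 CPM (counts scaled to library size), the strips lay apart from all cultures. The second component held 20.9%. Correlations of log2 CPM across genes, which are not independent replicates, ranged from 0.949 to 0.982 between P plate libraries, 0.988 to 0.991 in M plate, 0.973 to 0.983 in M scaffold and 0.980 to 0.991 in strips. P plate replicate 1 lay apart from its group, with 13800 CPM of the macrophage lysozyme Lyz2 against 2260 and 1590 in replicates 2 and 3. M scaffold replicate 3 also lay apart, with 530 CPM of the glucose transporter Slc2a1 against 84.8 and 73.9.

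**Figure D1:**
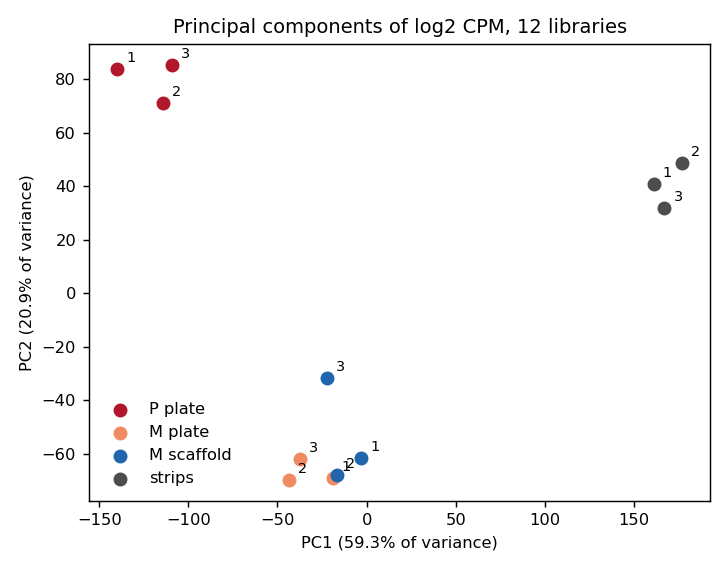
Principal components of log2 CPM over the tested genes, with the first component (59.3% of the variance) on the horizontal axis and the second (20.9%) on the vertical axis. Each point is 1 of the 12 libraries, coloured by group and numbered by replicate, and the 3 strips lie apart from the 9 cultures on the first axis.

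The comparison of M plate with P plate asked what the medium did to cells on a well plate. Endothelial genes were far higher in M plate: 10 of the 13 genes of the endothelium list rose, none fell and 3 did not pass, with a median log2 fold change of 6.51. Pecam1, an adhesion molecule of endothelial junctions, stood at 324 ± 23.0 CPM (SD, n = 3) in M plate and 0.416 ± 0.41 CPM in P plate, a log2 fold change of 9.55 ± 0.93 (SE). Genes of enteric neurons and of enteric glia, the neurons and support cells of the gut wall, also rose, in 16 of 20 and 10 of 13 genes, with medians of 3.40 and 2.27. Genes of the glycolysis and hypoxia list were lower in M plate, with 17 of 24 fallen and a median of -1.57. These lists passed at the preset correlation and not with an estimated correlation (adjusted p = 0.103, 0.103, 0.134 and 0.354). Across the genome 2532 genes were higher and 1868 lower in M plate among 17700 tested, of which 2022 and 575 differed by at least 2-fold.

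The endothelium list passed the test against other genes (camera adjusted p = 6.66e-14), though not with an estimated correlation (adjusted p = 0.103 with an estimated correlation). Adjusted over the list alone, 10 of its 13 genes were higher. Tie1, a receptor tyrosine kinase of blood and lymph vessels (ENSMUSG00000033191, GRCm38 chromosome 4, 118471191 to 118490061, minus strand), had a log2 fold change of 12.45 ± 1.08, and Cldn5, a claudin of endothelial tight junctions (ENSMUSG00000041378, chromosome 16, 18776847 to 18778262, plus strand), of 12.24 ± 1.16. Cdh5, the cadherin of endothelial junctions, rose by 10.23 ± 0.80. The T-box factor Tbx1 (ENSMUSG00000009097, chromosome 16, 18580979 to 18590671, minus strand) stood at 57.4 ± 4.17 CPM in M plate and had no counts in P plate, so it was at least 1920-fold higher against a floor of 3 counts over the group. The adhesion receptor Adgrl4 (ENSMUSG00000039167, chromosome 3, 151437887 to 151545086, plus strand) was at least 975-fold higher on the same floor, with 29.1 ± 5.32 CPM in M plate.

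In the enteric neuron list 18 of 20 genes were higher adjusted over the list alone (camera adjusted p = 2.14e-17, adjusted p = 0.103 with an estimated correlation). Nos1, the neuronal nitric oxide synthase, rose by 4.64 ± 0.48 on the log2 scale, the neuronal RNA-binding protein gene Elavl4 by 3.97 ± 0.40 and Calb2, which codes for calretinin, by 5.52 ± 0.72. Chat, which makes acetylcholine, was at least 20-fold higher, with no counts in P plate. The neuronal tubulin gene Tubb3 had a log2 fold change of 1.37 ± 0.55 and did not pass (adjusted p = 0.0974), but passed without P plate replicate 1 (2.40, adjusted p = 0.00247). Of the enteric glia list 10 of 13 genes were higher adjusted over the list alone (camera adjusted p = 3.11e-09, adjusted p = 0.134 with an estimated correlation). The ectonucleotidase gene Entpd2 rose by 3.29 ± 0.40 and Gfra3, a receptor for GDNF family ligands, rose by 4.22 ± 0.31.

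Fibroblast genes rose in 9 of 14 cases, or 10 adjusted over the list alone, with a median of 1.51 (camera adjusted p = 4.85e-07, adjusted p = 0.103 with an estimated correlation). Among them were Clec3b, the gene of tetranectin, at 7.76 ± 0.88, the dermatopontin gene Dpt at 6.58 ± 0.58 and the ferritin receptor gene Scara5 at 5.32 ± 0.79, while Pdgfra did not pass at -0.17 ± 0.46. Of the genes of interstitial cells of Cajal, the pacemaker cells of the gut, 5 of 8 rose, also adjusted over the list alone (median 1.30, camera adjusted p = 0.019, adjusted p = 0.257 with an estimated correlation). Kit, the receptor these cells need, rose by 5.08 ± 0.67 to 13.5 ± 2.63 CPM, and Prkcq, a protein kinase C gene, by 5.75 ± 0.81. In the pericyte list 4 genes rose and 1 fell of 8, with the same counts adjusted over the list alone, and the list test did not pass (adjusted p = 0.0899). Rgs5, a regulator of G protein signalling, rose by 2.59 ± 0.46 and the potassium channel subunit gene Abcc9 by 2.50 ± 0.36. Without P plate replicate 3 the pericyte list was called higher (adjusted p = 0.00192).

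Smooth muscle genes went both ways. In the excitation and signalling list 9 genes rose and 1 fell of 22, or 10 and 2 adjusted over the list alone, with a median of 0.789, or 1.29 without P plate replicate 1 (camera adjusted p = 0.000632, adjusted p = 0.354 with an estimated correlation). The muscarinic receptor gene Chrm2 rose by 3.92 ± 0.55 and the ATP-gated channel gene P2rx1 by 4.24 ± 0.69, while Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell by 0.80 ± 0.17. In the contractile list 5 genes rose and 4 fell of 24, or 6 and 4 adjusted over the list alone, and the list was not called (adjusted p = 0.944). Its median was -0.296 and its mean 0.325, and the test pointed down. Synm, an intermediate filament gene, rose by 4.89 ± 0.64 and the calmodulin-binding gene Pcp4 by 5.43 ± 0.80. Tagln, which binds actin filaments in smooth muscle, fell by 1.96 ± 0.42. The actin gene Acta2 fell by 1.21 ± 0.37 (adjusted p = 0.0354) and the desmin gene Des fell by 1.91 ± 0.54 (adjusted p = 0.0259). Acta2 did not pass without P plate replicate 1 or 3 (0.0557 and 0.115) or without M plate replicate 1, 2 or 3 (0.0782, 0.123 and 0.0622). Des did not pass without P plate replicate 3 (0.0972) or without M plate replicate 1, 2 or 3 (0.0544, 0.0963 and 0.0704). The myosin gene Myh11 had a log2 fold change of 0.54 ± 0.47 and the actin gene Actg2 of -0.46 ± 0.66, and neither passed (adjusted p = 0.44 and 0.656).

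Of the glycolysis and hypoxia list 21 of 24 genes were lower adjusted over the list alone (camera adjusted p = 2.61e-09, adjusted p = 0.354 with an estimated correlation). Slc2a1 fell by 3.16 ± 0.70 and the angiogenic factor gene Vegfa fell by 3.26 ± 0.68, from 363 ± 101 to 37.8 ± 8.68 CPM. YAP target genes fell in 10 of 22 cases and rose in 1, or 12 and 2 adjusted over the list alone, with a median of -0.727 (camera adjusted p = 0.000635, adjusted p = 0.257 with an estimated correlation). The ectonucleotidase gene Nt5e fell by 3.31 ± 0.47 and Ccn2, a matricellular growth factor gene, fell by 2.20 ± 0.35. In the list for p53 response and cell cycle arrest 8 genes fell and 1 rose of 16, or 9 and 1 adjusted over the list alone, with a median of -0.719 (camera adjusted p = 0.00508, adjusted p = 0.414 with an estimated correlation). The nuclease gene Aen of that list fell by 1.07 ± 0.16. Without P plate replicate 1 the list was not called (adjusted p = 0.102). The largest falls among genes with a mean of at least 20 CPM were those of Tnfrsf9, a receptor of the TNF family, at -7.25 ± 1.26, the arginase gene Arg1 at -6.85 ± 1.32, the involucrin gene Ivl at -6.27 ± 1.02, the chromatin protein gene Hmga2 at -4.87 ± 0.65 and Lrrc2 at -4.50 ± 0.83.

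Matrix genes split into 6 that rose and 5 that fell of 23, with the same counts adjusted over the list alone (median 0.062, adjusted p = 0.755). The collagen VI genes Col6a2 and Col6a1 rose by 3.33 ± 0.27 and 2.73 ± 0.23, and the tenascin gene Tnc fell by 2.11 ± 0.17. Of the matrix proteases and inhibitors 2 of 17 rose and 6 fell, or 2 and 8 adjusted over the list alone (median -0.864, adjusted p = 0.069). The aggrecanase gene Adamts5 rose by 1.75 ± 0.25. That list was called lower without P plate replicate 1 or 2 or M plate replicate 3 (adjusted p = 0.042, 0.0185 and 0.016), with a median of -0.55 without P plate replicate 1. Among TGF-beta targets 1 of 10 rose and 3 fell, or 1 and 4 over the list alone (median -0.384, adjusted p = 0.0911), and the list was called lower without P plate replicate 1 (0.042). The Wnt target list gave 3 higher and 1 lower of 12, or 4 and 2 over the list alone (adjusted p = 0.806). Its Wnt-inactivating enzyme gene Notum rose by 2.36 ± 0.38 and its receptor gene Lgr6 fell by 3.72 ± 0.56. BMP targets gave 3 higher and 1 lower of 12, or 3 and 2 over the list alone (adjusted p = 0.582), with a median of -0.141, a mean of 0.413 and a test that pointed up. The transcriptional repressor gene Hey1 of that list rose by 3.21 ± 0.33.

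Inflammatory mediators gave 1 higher and 2 lower of 16, also over the list alone (adjusted p = 0.21), with the prostaglandin synthase gene Ptgs2 at -4.34 ± 0.46. Lymphocyte genes rose in 3 of 6 cases and adipocyte genes in 3 of 8, also over the lists alone, and neither list passed (adjusted p = 0.0594 for both). With the genes that had no counts in P plate set at their floor, the adipocyte median was 0.923 in place of 1.70. The lymphocyte list was called without P plate replicate 1 or 2 or M plate replicate 1 (0.0379, 0.0349 and 0.0344), and the adipocyte list without P plate replicate 1 or M plate replicate 1 or 2 (0.042, 0.0335 and 0.0423). Cholesterol synthesis gave 3 higher of 22 (adjusted p = 0.812), epithelium 1 higher and 1 lower of 17 (0.755) and immediate early genes 1 lower of 15 (0.486). Over the lists alone these were 3, 1 and 0, and 1. In the mesothelium, macrophage, cell cycle, oxidative phosphorylation and interferon lists no gene of 80 passed edgeR, where 0 had an unadjusted p under 0.05, nor DESeq2 or limma-voom. Their adjusted p were 0.812, 0.405, 0.899, 0.18 and 0.962, with medians of 0.144, -0.646, 0.116, -0.11 and 0.209, and the interferon test pointed down. The macrophage marker Cd68 stood at 844 CPM in P plate replicate 1 against 197 and 108 in replicates 2 and 3, and the mesothelin gene Msln at 24.3 against 524 and 551. Msln was called lower in M plate without P plate replicate 1 (log2 fold change -0.9, adjusted p = 0.00504). Without P plate replicate 3 the macrophage list was called lower (median -1.09, adjusted p = 0.00496) and the cell cycle list higher (0.63 and 0.00242).

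Calls came from edgeR's quasi-likelihood F test on all 12 libraries with an adjusted p under 0.05. When single libraries were left out, the number of genes lower in M plate moved to 1140 without P plate replicate 3 and to 812, 879 and 1178 without M plate replicates 1, 2 and 3. Of the 46 genes named in this comparison that were called, 44 passed without each single library, and Acta2 and Des did not. The naming rule favoured large changes, so these genes do not stand for all called genes. Of all 4400 called genes, 2587 to 3786 stayed called in the same direction when a single library was left out. All 46 passed with the replicate number as a block in all 12 libraries. With the block within the 6 compared libraries 37 of the 46 passed. Elavl4 (0.0534), Calb2 (0.0538), Chat (0.0894), Chrm2 (0.0536), P2rx1 (0.076), Atp2a2 (0.0965), Arg1 (0.0638), Acta2 (0.0716) and Des (0.106) did not.

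**Figure D2:**
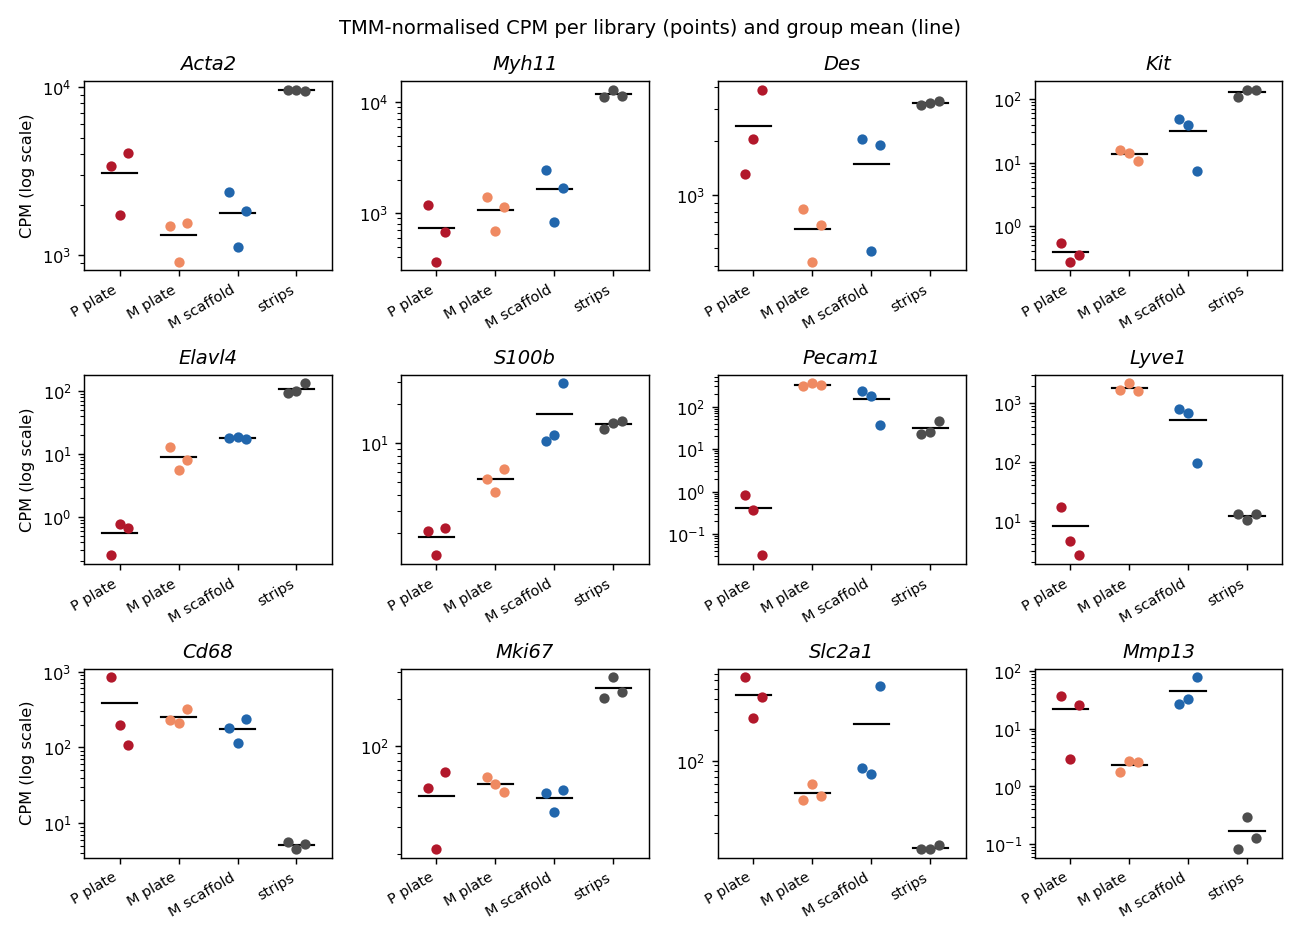
CPM on a log axis of 12 marker genes in each library, by group, with a line at the group mean of 3 libraries. Pecam1 lies at 324 ± 23.0 CPM in M plate and at 0.416 ± 0.41 CPM in P plate, and Slc2a1 at 49.1 ± 8.94 and 438 ± 195 CPM.

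The comparison of M scaffold with M plate asked what the gelatin scaffold did with the medium held the same. Fewer genes passed: 271 were higher and 291 lower on the scaffold, 210 and 215 of them by at least 2-fold. A2m, a broad protease inhibitor of plasma, rose by 3.45 ± 0.28 on the log2 scale to 1090 ± 321 CPM (SD, n = 3). Glial genes rose in 5 of 13 cases and neuronal genes in 2 of 20, with list medians of 1.18 and 1.10. Endothelial genes were lower as a list at the preset correlation, with a median of -1 and 1 gene of 13 called, but neither with an estimated correlation (adjusted p = 0.43) nor by fry (0.0721). The glial and neuronal lists, called at the preset correlation, did not pass with an estimated correlation either (0.16 for both), but passed by fry (0.0213 for both). With the replicate number as a block in all 12 libraries, 222 genes were higher and 169 lower, 333 of them shared with the fit without the block in the same direction. With the block within the 6 compared libraries, added after the data were seen, 787 were higher and 931 lower, 485 of them shared in the same way.

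The largest rises among well-read genes were those of A2m (ENSMUSG00000030111, chromosome 6, 121635376 to 121679227, plus strand), Mmp13, Apln, Ifi205 and Nfasc. The collagenase gene Mmp13 rose by 4.27 ± 0.80, the vascular peptide gene Apln by 2.88 ± 0.64, the interferon-inducible gene Ifi205 by 2.77 ± 0.55 and the neurofascin gene Nfasc by 2.6 ± 0.31. The largest falls among genes with a mean of at least 20 CPM were those of Tnfsf18, a ligand of the TNF family, at -5.41 ± 0.74, of Adamtsl2, a secreted glycoprotein gene (ENSMUSG00000036040, chromosome 2, 27079379 to 27108981, plus strand), at -3.64 ± 0.41, and of 3 further genes. These were the hyaluronan receptor gene Stab2 at -3.56 ± 0.72, Plvap, which codes for the diaphragm protein of endothelial fenestrae, at -3.35 ± 0.45 and the prominin gene Prom1 at -2.81 ± 0.47.

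Of the enteric glia list 7 of 13 genes were higher adjusted over the list alone (camera adjusted p = 8.41e-07, adjusted p = 0.16 with an estimated correlation). The calcium-binding protein gene S100b rose by 1.70 ± 0.37 and Foxd3, a neural crest factor, by 1.83 ± 0.36. Without M scaffold replicate 3 the S100b value was 1.06. In the enteric neuron list 10 of 20 were higher over the list alone (camera adjusted p = 2.17e-08, adjusted p = 0.16 with an estimated correlation), with the ubiquitin hydrolase gene Uchl1 up by 1.34 ± 0.30 and Syt1, a sensor of transmitter release, up by 1.21 ± 0.23. Of the interstitial cells of Cajal list 1 of 8 rose, or 3 over the list alone, with a median of 1.02 (camera adjusted p = 0.00211, adjusted p = 0.16 with an estimated correlation). Their chloride channel gene Ano1 rose by 1.07 ± 0.20. Kit, at 1.24 ± 0.51, did not pass (adjusted p = 0.198), but passed without M scaffold replicate 3 (0.0178). In the pericyte list 1 of 8 rose, or 3 over the list alone, with a median of 0.812 (camera adjusted p = 0.00102, adjusted p = 0.16 with an estimated correlation). Its potassium channel gene Kcnj8 rose by 2.00 ± 0.36.

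The contractile list was higher as a list, with a median of 0.825 (camera adjusted p = 8.61e-07, adjusted p = 0.512 with an estimated correlation). By edgeR 0 of its 24 genes passed, also adjusted over the list alone, while 13 had an unadjusted p under 0.05, all higher, and DESeq2 called 5 and limma-voom 0. Acta2, Myh11, Actg2 and Des had log2 fold changes of 0.43 ± 0.36, 0.63 ± 0.47, 1.33 ± 0.67 and 1.21 ± 0.52. In the excitation and signalling list 1 gene rose and 1 fell of 22, or 9 and 1 over the list alone, with a median of 0.616 (camera adjusted p = 0.0103, adjusted p = 0.512 with an estimated correlation). The potassium channel gene Kcnma1 rose by 1.23 ± 0.23 and P2rx1 fell by 5.59 ± 0.75. The list was not called without M plate replicate 2 (0.284) or M scaffold replicate 1 (0.306). Glycolysis and hypoxia genes were higher as a list, with 1 of 24 called, also over the list alone, and a median of 0.927 (camera adjusted p = 3.25e-05, adjusted p = 0.512 with an estimated correlation). The oxygen sensor gene Egln3 rose by 2.38 ± 0.54, or 1.41 without M scaffold replicate 3. Without M scaffold replicate 3, the library with 530 CPM of Slc2a1, the median was 0.26 and the list was not called (adjusted p = 0.0679). Matrix proteases and inhibitors had 2 of 17 higher, or 8 higher and 2 lower over the list alone, with a median of 0.54 (camera adjusted p = 0.00139, adjusted p = 0.16 with an estimated correlation). The plasminogen activator gene Plat rose by 0.94 ± 0.17.

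Endothelial genes gave 0 higher and 1 lower of 13, also over the list alone (camera adjusted p = 0.00139, adjusted p = 0.43 with an estimated correlation), and Emcn, an endothelial sialomucin gene, fell by 2.64 ± 0.49. Pecam1, at -1.13 ± 0.62, did not pass (adjusted p = 0.331), and stood at 37.0 CPM in M scaffold replicate 3 against 235 and 175 in replicates 1 and 2. The macrophage list had a median of -0.987 (camera adjusted p = 0.00139, adjusted p = 0.512 with an estimated correlation). By edgeR 0 of its 16 genes passed, also over the list alone, while 3 had an unadjusted p under 0.05, all lower, and DESeq2 called 2 and limma-voom 0. The lymphocyte list had 1 of 6 lower, or 2 over the list alone, with a median of -2.00 (camera adjusted p = 0.00524, adjusted p = 0.16 with an estimated correlation). The B cell receptor gene Cd79b fell by 2.68 ± 0.61. Of the YAP targets 3 of 22 fell, or 5 higher and 8 lower over the list alone, with a median of -0.305 (camera adjusted p = 0.032, adjusted p = 0.512 with an estimated correlation). Ccn2 fell by 1.51 ± 0.34 and Crim1, a transmembrane regulator of growth factors, fell by 1.35 ± 0.27. That list was not called without M plate replicate 3 (0.0557) or M scaffold replicate 1 or 2 (0.0939 and 0.053). BMP targets had a median of -0.56 (camera adjusted p = 0.00863, adjusted p = 0.512 with an estimated correlation), with 2 of 12 lower over the list alone, and were not called without M scaffold replicate 3 (0.153).

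Higher as lists were also oxidative phosphorylation (median 0.207, camera adjusted p = 0.00479), immediate early genes (0.579 and 0.00405) and p53 response (0.335 and 0.0221). With an estimated correlation their adjusted p were 0.512, 0.512 and 0.531, and over the lists alone 0 of 20, 4 of 15 and 1 of 16 genes were higher. Immediate early genes were not called without M plate replicate 1 (0.064), nor p53 response without M scaffold replicate 3 (0.12). Lists not called were fibroblasts (0.61), mesothelium (0.0969), epithelium (0.918), adipocytes (0.467), cell cycle (0.542), extracellular matrix (0.399), Wnt targets (0.484), TGF-beta targets (0.72), cholesterol synthesis (0.0876), inflammatory mediators (0.503) and interferon (0.0937). The Wnt target list had a median of -0.0331 and a mean of 0.489, and its feedback gene Nkd2 rose by 1.28 ± 0.25. With genes at no counts set at their floor the adipocyte median was -0.0298 in place of 0.337. The mesothelium list was called lower in the 6 libraries alone (0.00132), with the block within them (0.000275) and without the 3 libraries that stood apart (0.00488). The interferon list was called lower with the replicate block (0.0114) and without M plate replicate 3 or M scaffold replicate 2 (0.0081 and 1.93e-08). Cholesterol synthesis was called lower without M plate replicate 2 or M scaffold replicate 3 (0.0113 and 0.000143), and inflammatory mediators higher without M scaffold replicate 1 (0.0273). In the 12 lists with no called gene by edgeR, 41 of 186 genes had an unadjusted p under 0.05, DESeq2 called 15 higher and 4 lower, and limma-voom 1 higher and 0 lower.

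Residuals of same-numbered M scaffold and M plate libraries correlated across genes at 0.29, 0.20 and 0.30 (highest other pair -0.06), hence the replicate block given beside the counts. Residuals were taken from the group means, so positive values in same-numbered pairs push the other pairs down. The other pairs are thus no independent evidence of pairing. Single libraries weighed heavily in this comparison: the counts higher and lower were 86 and 60 without M plate replicate 1, 7 and 11 without replicate 2 and 24 and 30 without replicate 3. Without M scaffold replicates 1, 2 and 3 they were 177 and 131, 225 and 123, and 103 and 111. Of the 27 genes named in this comparison that were called, A2m, Adamtsl2 and P2rx1 passed without each single library. Without M plate replicates 1, 2 and 3, 9, 3 and 6 of the 27 passed, and without M scaffold replicates 1, 2 and 3, 13, 19 and 13. With the replicate block 20 of the 27 passed, and Apln (0.0768), Ifi205 (0.0606), Kcnma1 (0.0511), Egln3 (0.0814), Cd79b (0.0738), Ccn2 (0.0542) and Crim1 (0.0516) did not. With the block within the 6 libraries 25 of the 27 passed, and Egln3 (0.0972) and Cd79b (0.0782) did not. Medians of called lists also moved by over 1.5 times with single libraries. Without M scaffold replicate 3 that of endothelium was -0.54, of YAP targets -0.15, of BMP targets -0.37, of immediate early genes 0.35 and of p53 response 0.22. Without M scaffold replicate 1 endothelium stood at -1.6, pericytes at 0.5 and excitation and signalling at 0.35. Without M plate replicate 1 YAP targets stood at -0.18 and immediate early genes at 0.28, and without M plate replicate 2 immediate early genes at 0.32 and excitation and signalling at 0.39.

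Comparing P plate with strips asked how cells grown in serum differed from native muscle. Muscle, pacemaker and nerve genes were lower in the culture: 21 of 24 contractile genes and all 20 neuronal genes fell, with median log2 fold changes of -1.82 and -7.13. The smooth muscle myosin gene Myh11 stood at 744 ± 412 CPM (SD, n = 3) in P plate and 11900 ± 959 CPM in strips, a log2 fold change of -4.00 ± 0.53. Macrophage genes, matrix proteases and inflammatory mediators were higher, in 15 of 16, 17 of 17 and 15 of 16 genes, with medians of 5.49, 3.58 and 5.10. Of these lists only the matrix proteases also passed with an estimated correlation (adjusted p = 0.0279). In all, 5390 genes were higher and 5785 lower in P plate, 2716 and 4287 of them by at least 2-fold.

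The contractile list, with 21 lower also over the list alone, and the excitation and signalling list, with 17 of 22 lower also over the list alone and a median of -2.49, had the same adjusted p (3.69e-06, and adjusted p = 0.398 and 0.294 with an estimated correlation). Synm fell by 7.87 ± 0.73, the muscle coactivator gene Myocd fell by 5.98 ± 0.78, Acta2 fell by 1.64 ± 0.37 and Actg2 fell by 3.31 ± 0.72, while Tagln and Des did not pass at -0.26 ± 0.41 and -0.43 ± 0.52. The tachykinin receptor gene Tacr2 fell by 9.57 ± 0.82 and the calcium store gene Casq2 fell by 6.38 ± 0.44. Of the interstitial cells of Cajal list 6 of 8 fell, also over the list alone (median -4.75, camera adjusted p = 6.66e-05, adjusted p = 0.114 with an estimated correlation), with Kit at -8.35 ± 0.73 and Ano1 at -3.68 ± 0.22. The receptor gene Cckar had no counts in P plate and was at least 1440-fold lower. For neurons all 20 fell, also over the list alone (camera adjusted p = 1.72e-19, adjusted p = 0.114 with an estimated correlation). Among them were the neurofilament gene Nefl at -9.68 ± 0.56, Elavl4 at -7.59 ± 0.45 and Tubb3 at -3.60 ± 0.60. For glia 11 of 13 fell and 1 rose, also over the list alone (median -2.74, camera adjusted p = 0.00108, adjusted p = 0.342 with an estimated correlation), with Gfra3 up by 1.56 ± 0.34. Endothelial genes gave 8 lower and 1 higher of 13, or 9 and 1 over the list alone (median -2.13, camera adjusted p = 0.0119, adjusted p = 0.448 with an estimated correlation), with Tie1 at -8.10 ± 1.04 and Pecam1 at -6.19 ± 0.84.

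Macrophage genes were higher in the same 15 cases over the list alone (camera adjusted p = 6.43e-06, adjusted p = 0.367 with an estimated correlation), with Lyz2 up by 6.93 ± 0.94 and Cd68 by 6.19 ± 0.75. Without P plate replicate 1 these were 5.27 for Lyz2 and 4.83 for Cd68. The matrix protease list held with an estimated correlation (camera adjusted p = 1.7e-09, adjusted p = 0.0279 with an estimated correlation), with all 17 higher also over the list alone. In it the stromelysin gene Mmp3 rose by 9.38 ± 0.95 and the macrophage elastase gene Mmp12 by 10.39 ± 1.09. Inflammatory mediators were higher in 16 of 16 over the list alone (camera adjusted p = 2.36e-06, adjusted p = 0.294 with an estimated correlation), with the acute phase gene Saa3 up by 9.14 ± 0.70. Matrix genes rose in 14 and fell in 4 of 23, also over the list alone (median 1.14, camera adjusted p = 0.000401, adjusted p = 0.342 with an estimated correlation), with Thbs1, the thrombospondin gene, up by 6.34 ± 0.30 and Col6a2 at -2.98 ± 0.26. In p53 response and cell cycle arrest 15 of 16 rose, also over the list alone (median 2.23, camera adjusted p = 3.18e-07, adjusted p = 0.277 with an estimated correlation). The cell cycle inhibitor genes Cdkn2a and Cdkn2b rose by 5.49 ± 0.49 and 5.74 ± 0.58. All 22 cell cycle genes fell, also over the list alone (median -1.81, camera adjusted p = 0.000401, adjusted p = 0.476 with an estimated correlation), with the proliferation marker Mki67 at -2.30 ± 0.34.

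Glycolysis and hypoxia genes rose in 21 of 24 cases, or 22 over the list alone (median 2.36, camera adjusted p = 3.6e-06, adjusted p = 0.398 with an estimated correlation), with Slc2a1 up by 4.93 ± 0.76. Oxidative phosphorylation genes fell in 17 of 20, also over the list alone (median -0.859, camera adjusted p = 2.26e-05, adjusted p = 0.336 with an estimated correlation), with Ndufb8, a subunit of respiratory complex I, at -2.19 ± 0.14. Mitochondrially encoded genes took 2.22% to 3.76% of the counts in strips and 1.11% to 1.55% in the cultures. YAP targets gave 15 higher and 2 lower of 22, and TGF-beta targets 7 and 2 of 10, also over the lists alone (medians 1.34 and 1.70, camera adjusted p = 0.000112 and 0.012, adjusted p = 0.277 and 0.294 with an estimated correlation). Igfbp3, a carrier of insulin-like growth factors, rose by 6.61 ± 0.57. Interferon genes rose in 8 of 14 and immediate early genes in 10 of 15, also over the lists alone (medians 1.77 and 1.36, camera adjusted p = 0.00547 and 0.000617, adjusted p = 0.476 and 0.342 with an estimated correlation). The tetherin gene Bst2 rose by 3.62 ± 0.39 and the AP-1 gene Junb by 4.17 ± 0.27. Epithelial genes gave 11 lower and 1 higher of 17, or 11 and 2 over the list alone (median -5.44, camera adjusted p = 0.0123, adjusted p = 0.476 with an estimated correlation), and were not called without P plate replicate 1 (0.071). The enterocyte phosphatase gene Alpi, without counts in P plate and at least 2940-fold lower there, or 635-fold without strips replicate 2, read 14.9, 225 and 23.0 CPM in strips replicates 1 to 3.

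Lists not called were fibroblasts (4 higher and 6 lower of 14, adjusted p = 0.306), pericytes (2 and 5 of 8, 0.247), mesothelium (2 and 1 of 8, 0.946), lymphocytes (1 and 2 of 6, 0.608), adipocytes (2 and 5 of 8, 0.195), Wnt targets (1 and 6 of 12, 0.169), BMP targets (5 and 4 of 12, 0.306) and cholesterol synthesis (6 and 5 of 22, 0.272). Over the lists alone the pericyte count of higher genes was 3 and the mesothelium count 0, and the other counts were the same. The mesothelium median was -0.0665 while its test pointed up, and the lymphocyte median was -0.487 in place of -1.22 with genes at no counts set at their floor. BMP targets were called higher without P plate replicate 1 (0.0361), pericytes lower without P plate replicate 3 (0.0387) and adipocytes lower without strips replicate 2 (0.0274). Scaled by library totals alone, 33.4% of called genes were higher in P plate in place of 48.2%, and the median of all genes moved to -0.30. All 33 called genes named in this comparison passed without each single library. Of all 11175 called genes, 9843 to 10315 stayed called in the same direction.

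Comparing M plate with strips asked the same of cells in differentiation medium. Contractile, pacemaker and neuronal genes were lower than in muscle, in 23 of 24, 5 of 8 and 20 of 20 genes, with median log2 fold changes of -2.34, -2.43 and -3.51. Myh11 stood at 1080 ± 356 CPM (SD, n = 3) in M plate, a log2 fold change of -3.46 ± 0.52 against strips. Endothelial genes were higher, in 10 of 13 cases with 2 lower and a median of 3.38, as were macrophage genes, in 15 of 16 with a median of 4.75. None of these lists passed with an estimated correlation (adjusted p = 0.11 to 0.272). Counts of called genes were 4687 higher and 5025 lower, 2491 and 3392 of them by at least 2-fold.

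In the contractile list all 23 fell over the list alone too (camera adjusted p = 3.39e-09, adjusted p = 0.272 with an estimated correlation), with Actg2 at -3.77 ± 0.74, Acta2 at -2.85 ± 0.39, Des at -2.34 ± 0.54 and Tagln at -2.22 ± 0.43. The excitation and signalling list gave 14 lower and 1 higher of 22, also over the list alone (median -1.61, camera adjusted p = 0.000286, adjusted p = 0.272 with an estimated correlation), with Tacr2 at -6.91 ± 0.67 and P2rx1 up by 2.51 ± 0.62. For interstitial cells of Cajal, 5 lower also over the list alone, the test passed (camera adjusted p = 0.000268, adjusted p = 0.11 with an estimated correlation), with Kit at -3.27 ± 0.55, Ano1 at -3.00 ± 0.22 and the orphan receptor gene Gpr20 at -3.90 ± 0.48. For neurons, 20 lower also over the list alone, it passed too (camera adjusted p = 4.02e-13, adjusted p = 0.11 with an estimated correlation), with the substance P gene Tac1 at -5.64 ± 0.45 and Elavl4 at -3.62 ± 0.36. Glial genes went both ways, with 4 higher and 5 lower of 13, or 4 and 6 over the list alone (adjusted p = 0.921). Gfra3 rose by 5.78 ± 0.34 and the fatty acid carrier gene Fabp7 fell by 4.52 ± 0.57, while Gfap did not pass at 0.06 ± 0.44.

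The endothelium list gave 10 higher and 2 lower over the list alone too (camera adjusted p = 0.00164, adjusted p = 0.272 with an estimated correlation), with the hyaluronan receptor gene Lyve1 up by 7.25 ± 0.96, Tie1 by 4.35 ± 0.67 and Pecam1 by 3.37 ± 0.67. Macrophage genes were higher in 15 cases over the list alone too (camera adjusted p = 2.13e-07, adjusted p = 0.272 with an estimated correlation), with the macrophage receptor gene Adgre1 up by 5.69 ± 0.84 and Cd68 by 5.59 ± 0.73. Fibroblast genes rose in 5 of 14, also over the list alone (median 1.07, camera adjusted p = 0.0246, adjusted p = 0.272 with an estimated correlation), with the lumican gene Lum up by 3.19 ± 0.52 and Pdgfra by 3.04 ± 0.49, and the list was not called without strips replicate 2 (0.0535). Matrix proteases rose in 15 of 17, or 16 over the list alone (median 3.47, camera adjusted p = 1.99e-10, adjusted p = 0.0267 with an estimated correlation), with Mmp3 up by 8.29 ± 0.93. Matrix genes rose in 14 of 23, also over the list alone (median 1.14, camera adjusted p = 4.7e-07, adjusted p = 0.218 with an estimated correlation), with the crosslinking enzyme gene Lox up by 4.06 ± 0.21. Among the largest rises of well-read genes were those of Saa3 at 10.61 ± 0.74, Serpind1, a thrombin inhibitor gene, at 10.36 ± 1.63 and the chemokine gene Ccl8 at 10.16 ± 2.03.

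Inflammatory mediators, p53 response, immediate early and interferon genes rose in 15 of 16, 15 of 16, 12 of 15 and 9 of 14 cases, or 15, 15, 12 and 13 over the lists alone, with medians of 4.45, 1.42, 1.41 and 1.94 (camera adjusted p = 5.34e-07, 4.33e-06, 0.00046 and 0.000818, adjusted p = 0.272, 0.272, 0.272 and 0.46 with an estimated correlation). Cell cycle and oxidative phosphorylation genes fell in 21 of 22 and 18 of 20, or 22 and 18 over the lists alone, with medians of -1.69 and -0.964 (camera adjusted p = 5.94e-05 and 2.59e-09, adjusted p = 0.457 and 0.218 with an estimated correlation). Mki67 fell by 2.05 ± 0.34 and Ndufb8 fell by 2.25 ± 0.14. YAP targets gave 11 higher and 3 lower of 22 and TGF-beta targets 7 and 2 of 10, also over the lists alone, with medians of 0.869 and 1.14 (camera adjusted p = 0.00891 and 0.041, adjusted p = 0.272 for both with an estimated correlation). TGF-beta targets were not called without strips replicate 1 or 3 (0.0575 and 0.0557). Epithelial genes fell in 13 and rose in 1 of 17, also over the list alone (median -5.86, camera adjusted p = 0.000526, adjusted p = 0.312 with an estimated correlation). Glycolysis, with 7 higher and 2 lower of 24 or 5 and 2 over the list alone, was not called (0.0625), but was called higher without M plate replicate 1 (0.0282) and with library totals alone (0.0238). Pericytes (2 higher and 5 lower of 8, adjusted p = 0.657), mesothelium (1 and 1 of 8, 0.732), lymphocytes (2 and 1 of 6, 0.437), adipocytes (2 and 5 of 8, 0.543), Wnt targets (0 and 7 of 12, 0.122), BMP targets (6 and 1 of 12, 0.0809) and cholesterol synthesis (6 and 0 of 22, 0.0979) were not called. Over the lists alone the mesothelium counts were 0 and 0 and that of cholesterol synthesis 5, and the others were the same. BMP targets (0.0479) and cholesterol synthesis (0.0478) were called higher without M plate replicate 2. Library totals alone gave 33.9% of called genes higher in place of 48.3%, with the median of all genes at -0.23. The 34 called genes named for this comparison all passed without each single library. Of all 9712 called genes, 8090 to 8434 stayed called in the same direction.

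Comparing M scaffold with strips asked how the scaffold cultures differed from muscle. Contractile genes fell in 18 of 24 cases and neuronal genes in 16 of 20, with median log2 fold changes of -1.42 and -2.67. Myh11 stood at 1670 ± 820 CPM (SD, n = 3), a log2 fold change of -2.83 ± 0.50. Of glial genes 6 rose and 3 fell of 13, with a median of 0.618 that was 0.13 without M scaffold replicate 3, and fibroblast genes rose in 8 of 14 and fell in 1, with a median of 1.36. With an estimated correlation none of these 4 lists passed (adjusted p = 0.404 for contractile genes, 0.214 for neurons, 0.458 for glia and 0.223 for fibroblasts). In all, 4344 genes were higher and 4884 lower, 2186 and 3282 of them by at least 2-fold.

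The contractile list had 19 lower over the list alone (camera adjusted p = 9.22e-06, adjusted p = 0.404 with an estimated correlation), with Acta2 at -2.43 ± 0.38 and Pcp4 at -4.77 ± 0.53, while Des did not pass at -1.14 ± 0.52. Excitation and signalling genes fell in 13 of 22, or 14 over the list alone (median -1.28, camera adjusted p = 0.0032, adjusted p = 0.404 with an estimated correlation), with Tacr2 at -6.27 ± 0.64. Genes of interstitial cells of Cajal fell in 4 of 8, also over the list alone (median -1.72, camera adjusted p = 0.00539, adjusted p = 0.214 with an estimated correlation), with Ano1 at -1.93 ± 0.21 and Kit at -2.03 ± 0.52. Kit read 7.41 CPM in M scaffold replicate 3 against 49.7 and 38.7 in replicates 1 and 2. The neuron list, 16 lower also over the list alone, passed (camera adjusted p = 4.28e-09, adjusted p = 0.214 with an estimated correlation), with Nefl at -5.63 ± 0.42 and Elavl4 at -2.6 ± 0.34, while Tubb3 did not pass at -1 ± 0.54. Tubb3 was called lower in the 6 compared libraries alone (adjusted p = 0.00765) and with the replicate block within them (0.00587). It was also called without the 3 libraries that stood apart (0.0271), and not in the other alternatives. In the glia list, with the same counts over the list alone (camera adjusted p = 0.0446, adjusted p = 0.458 with an estimated correlation), the cadherin gene Cdh19 rose by 3.13 ± 0.30 and Gfra3 by 6.03 ± 0.34. The list was not called without M scaffold replicate 3 (0.128) or strips replicate 1 (0.0803).

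The fibroblast list had 8 higher and 2 lower over the list alone (camera adjusted p = 0.00864, adjusted p = 0.223 with an estimated correlation), with Lum up by 3.94 ± 0.53. Without M scaffold replicate 3 its median was 0.62. Without the 3 libraries that stood apart its median was 0.52 and the list was not called (camera adjusted p = 0.164). Endothelial genes gave 9 higher and 3 lower of 13, also over the list alone (median 2.57, camera adjusted p = 0.0389, adjusted p = 0.458 with an estimated correlation), with Lyve1 up by 5.45 ± 0.88 and Flt1, a VEGF receptor gene, by 4.43 ± 0.62. Lyve1 read 96.3 CPM in M scaffold replicate 3 against 803 and 680 in replicates 1 and 2. That list was not called without M scaffold replicate 1 or 2 or strips replicate 2 (0.0678, 0.0694 and 0.064). Macrophage genes rose in 12 of 16, or 13 over the list alone (median 3.82, camera adjusted p = 6.32e-06, adjusted p = 0.378 with an estimated correlation), and matrix proteases in 15 of 17, or 16 over the list alone (median 3.37, camera adjusted p = 1.16e-15, adjusted p = 0.00445 with an estimated correlation). Cd14, a receptor for bacterial lipopolysaccharide, rose by 5.27 ± 0.37 and Mmp13 by 8.24 ± 1.03. Matrix genes rose in 16 of 23, also over the list alone (median 0.988, camera adjusted p = 4.28e-09, adjusted p = 0.214 with an estimated correlation), with the proteoglycan gene Bgn up by 4.31 ± 0.33. The serpin gene Serpina3i had no counts in strips and was at least 1100-fold higher on the scaffold, or 712-fold without M scaffold replicate 2.

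Inflammatory mediators, p53 response, immediate early, interferon and glycolysis genes rose in 14 of 16, 15 of 16, 13 of 15, 8 of 14 and 19 of 24 cases, or 14, 15, 14, 8 and 22 over the lists alone. Their medians were 5.17, 1.67, 1.62, 1.64 and 1.60 (camera adjusted p = 1.02e-07, 4.28e-09, 4.14e-07, 0.00468 and 7.68e-05, adjusted p = 0.223, 0.214, 0.214, 0.496 and 0.458 with an estimated correlation). Cell cycle and oxidative phosphorylation genes fell in 21 of 22 and 17 of 20, or 21 and 18 over the lists alone, with medians of -1.97 and -0.732 (camera adjusted p = 3.9e-06 and 1.95e-07, adjusted p = 0.421 and 0.223 with an estimated correlation), and Mki67 fell by 2.34 ± 0.34. Without M scaffold replicate 2 the interferon median was 0.64, and without M scaffold replicate 3 that of glycolysis was 0.83. TGF-beta targets gave 7 higher and 2 lower of 10, also over the list alone (median 1.28, camera adjusted p = 0.017, adjusted p = 0.223 with an estimated correlation). Epithelial genes gave 12 lower and 1 higher of 17, also over the list alone (median -5.85, camera adjusted p = 0.00022, adjusted p = 0.378 with an estimated correlation). YAP targets, with 9 higher and 4 lower of 22, were not called (0.0619), but were called higher without M scaffold replicate 1 or 3 (0.0375 and 0.0348) and with library totals alone (0.0355). Pericytes (3 higher and 3 lower of 8, adjusted p = 0.356), mesothelium (0 and 2 of 8, 0.742), lymphocytes (2 and 2 of 6, 0.813), adipocytes (3 and 4 of 8, 0.742), Wnt targets (0 and 7 of 12, 0.187), BMP targets (4 and 4 of 12, 0.517) and cholesterol synthesis (4 and 1 of 22, 0.339) were not called. Over the lists alone there was 1 Wnt target higher, 5 BMP targets higher and 0 cholesterol genes lower, and the other counts were the same. Library totals alone gave 30.8% of called genes higher in place of 47.1%, with the median of all genes at -0.26. Each of the 20 called genes named here passed without each single library. Of all 9228 called genes, 7504 to 8020 stayed called in the same direction.

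**Figure D3:**
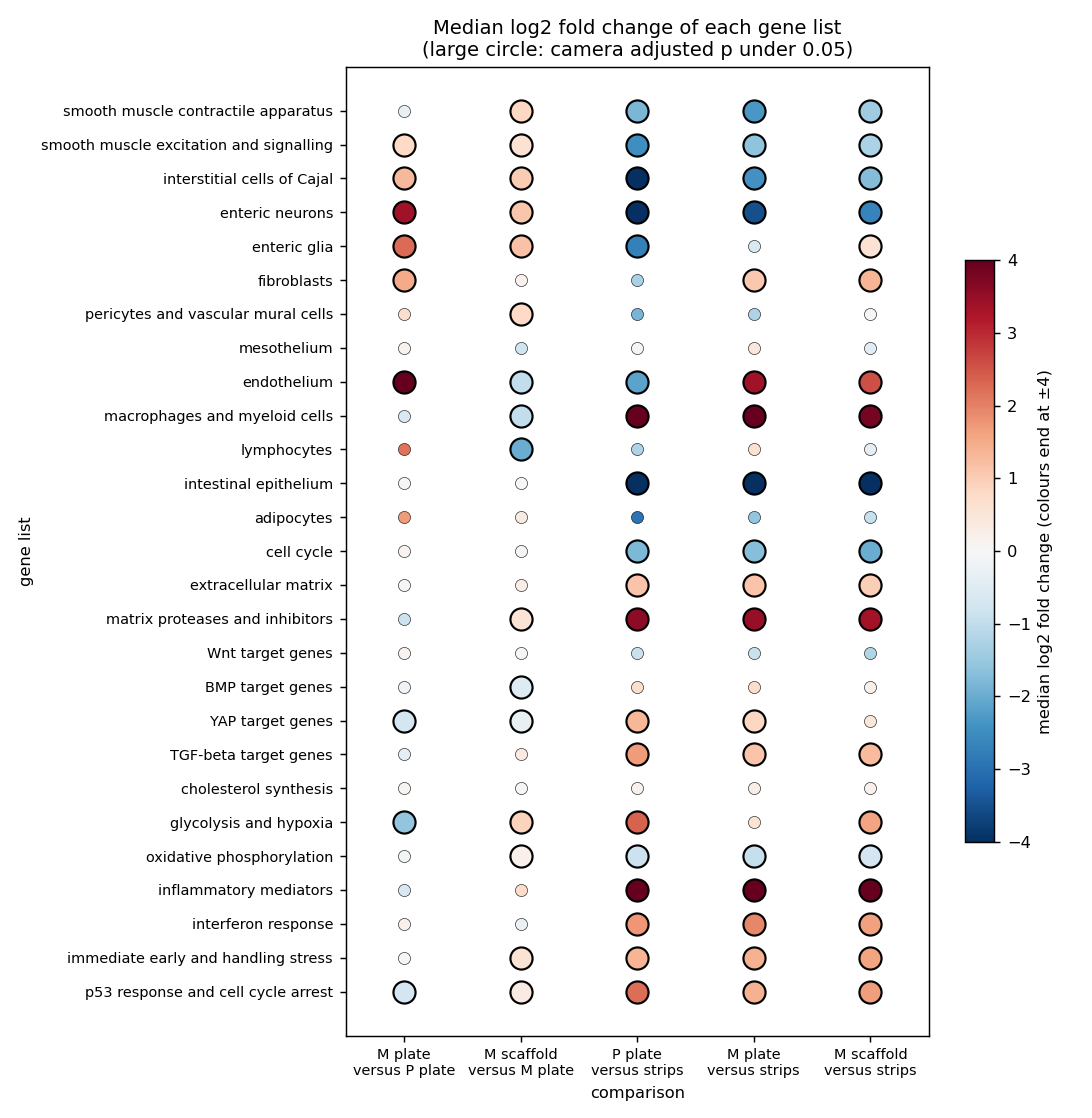
Median log2 fold change of each of the 27 gene lists in each of the 5 comparisons, shown by colour (red above 0, blue below), with a large circle where the camera adjusted p at the preset correlation is under 0.05. The neuron list runs from -7.13 in P plate against strips to 3.40 in M plate against P plate.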

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

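Of the tests in this part, the block within 6 libraries, the thinning to the smallest library, the omission of 3 libraries together and the list tests within 6 libraries and with library totals were chosen after the result was seen. Of counts of genes or lists under an alternative, 283 stayed within 1.5 times the reported count and 57 moved further. Of list results 1839 stayed on the same side of the threshold, 117 no longer passed and 69 newly passed. Of named gene results 3222 stayed, 175 no longer passed and 20 newly passed. No direction of a passed result reversed. In M plate against P plate the genes lower were 1187 without a low-count filter and 1116 in the 6 compared libraries alone, while higher and lower counts were 942 and 358 with the block within these and 1176 and 132 at a minimum fold of 2. Without single libraries, genes lower ranged from 812 to 2213. In M scaffold against M plate, higher and lower were 1146 and 873 by DESeq2 and 459 and 545 by limma-voom. They were 455 and 613 in the 6 libraries alone, 787 and 931 with the block within them, 3 and 4 at a minimum fold of 2, 134 and 141 when thinned, and 547 and 510 without 3 libraries that stood apart. The block in all 12 libraries gave 169 lower, and single omissions 7 to 225 higher and 11 to 131 lower. Against strips, a minimum fold of 2 gave 1669 and 3209 in P plate, 1504 and 2335 in M plate and 1211 and 1947 in M scaffold, and the block within 6 libraries 3374 higher in P plate. Lists called higher and lower, 6 and 3, 11 and 5, 10 and 9, 11 and 7, and 12 and 7 in the 5 comparisons in the order of the report, were 0 and 0, 0 and 0, 1 and 0, 1 and 0, and 1 and 0 with an estimated correlation. By fry, 5 lists were lower in M plate against P plate, 5 higher and 1 lower in M scaffold against M plate and 14 lower in P plate against strips. The other counts by fry stayed within 1.5 times the reported counts. Among these were the lists higher in M plate against P plate and in P plate against strips. Fewer libraries, fewer residual degrees of freedom and a stricter hypothesis are part of those alternatives, and the cause was not tested for the others. In the simulation 41% of genes changed 2-fold were recovered, so smaller changes can be missed at this number of libraries.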

Other observations

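Of the tests in this part, those on reads outside exons, on pools of animals, on X-linked paralogs, on villous enterocytes and on the mix of epithelial cells were chosen after the result was seen. The gene lists of this part were drawn up after a first look at the data. Of 12 lymphatic genes, of which the endothelium list also held Lyve1, 11 were higher in M plate than in P plate, with a median log2 fold change of 8.80, and 11 were higher than in strips, with a median of 6.23. Prox1, the factor that sets lymphatic identity, stood at 226 ± 20.6 CPM (SD, n = 3) in M plate, 0.816 ± 0.097 in P plate and 4.78 ± 2.15 in strips. Reln rose by 6.70 ± 0.48 (SE, log2) and Mmrn1, a platelet and endothelial matrix gene, by 6.97 ± 0.81 against strips. In M scaffold 11 of the 12 were higher than in strips as well, with a median of 4.20, while against M plate 2 were called lower and none higher, with a median of -1.62. Prox1 read 15.1 CPM in M scaffold replicate 3 against 155 and 77.4 in replicates 1 and 2. Of 12 genes of blood vessels 5 were higher in M plate than in P plate, with a median of 1.76. Against strips 2 of them were higher and 5 lower in M plate, with a median of -0.11, among them Vwf, the von Willebrand factor gene, at -3.23 ± 0.76. In M scaffold 1 was higher and 7 lower than in strips, with a median of -1.58, and 3 were called lower than in M plate, with a median of -0.54. In P plate against strips 1 lymphatic gene was higher and 8 lower, and 1 and 9 of the blood vessel genes, with medians of -2.72 and -4.12. A difference between the lymphatic and the blood vessel lists was not tested.

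The imprinted growth genes H19 and Igf2 were higher in cultures with M medium than in strips. H19, a long noncoding RNA of fetal tissues, stood at 2370 ± 384 CPM in M plate, 4960 ± 678 in M scaffold, 232 ± 63.4 in P plate and 459 ± 116 in strips, with log2 fold changes of 3.36 ± 0.29 for M plate against P plate and 2.37 ± 0.28 and 3.44 ± 0.29 for M plate and M scaffold against strips. In P plate it was lower than in strips, at -0.98 ± 0.26. That call did not pass with the replicate block within the 6 libraries (-1.03, adjusted p = 0.0677) or at a minimum fold of 2 (0.631). Igf2 did not pass in M plate against P plate (1.03 ± 0.43, adjusted p = 0.105) or in P plate against strips, where it pointed up (0.78 ± 0.42, adjusted p = 0.131). This fetal growth factor gene rose by 1.81 ± 0.44 and 2.78 ± 0.45 in M plate and M scaffold against strips. Between M scaffold and M plate H19 and Igf2 differed by 1.06 ± 0.27 and 0.97 ± 0.43 and did not pass (adjusted p = 0.0576 and 0.223). Both passed in the 6 compared libraries alone (0.0396 and 0.0313), with the replicate block within these (0.0386 and 0.0357) and without the 3 libraries that stood apart (0.0317 and 0.034). H19 also passed by DESeq2 (0.000868) and without a low-count filter (0.0476). Over all alternatives the adjusted p ran from 0.000868 for H19 and 0.0313 for Igf2 up to 1 for both, at a minimum fold of 2.

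Of 20 RNAs kept in the nucleus, a list without a list test, 11 were called lower in M scaffold than in M plate and 9 did not pass, with a median log2 fold change of -0.988, while 8 were called lower with the replicate block and 16 with the block within the 6 libraries. Without M plate replicates 1, 2 and 3, 3, 0 and 0 were called lower, and without M scaffold replicates 1, 2 and 3, 1, 3 and 6, with medians of -1.07 to -0.928 and all 20 below 0 in each case; Malat1, at -1.83 ± 0.33, did not pass without M plate replicate 1, 2 or 3 (adjusted p = 0.0714, 0.076 and 0.0675) or M scaffold replicate 1 or 2 (0.0627 and 0.0639), nor Leng8, at -1.35 ± 0.20, without M plate replicate 2 or 3 (0.073 and 0.0565). A trend of GC content and transcript length is argued against, since the median of the list was -0.986 after it was taken out, with an SD of 0.422. A smaller share of nuclear RNA in the scaffold extracts may explain values lower than in M plate. Lower values were not particular to the scaffold. Against strips, 18 of the 20 were called lower in M scaffold, 11 in P plate and 5 in M plate. In the same order 0, 2 and 2 were called higher, with medians of -1.16, -0.685 and -0.185. The list also holds protein-coding genes such as Leng8, Ogt and Pnisr, so it is not a class of noncoding RNA. Of 196 intergenic noncoding RNA genes outside the list, 5 were called lower and 2 higher, with a median of -0.195. Their median lay below that of protein-coding genes in all 9 pairings of libraries, by -0.278 to -0.164. Fewer reads outside exons also stay open, as does an untested biological change on the scaffold, with at most 5.12% in M scaffold and at least 5.73% in M plate (means 4.81 ± 0.32 and 6.09 ± 0.35, exact two-sided permutation p = 0.1, the smallest possible).

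Both Xist and Y-linked genes were read in all 12 libraries, with 15.5 to 121 Y-linked counts per 100 Xist counts, and replicate 2 was the lowest in every group, at 23.4 in P plate, 15.5 in M plate, 20 in M scaffold and 23.0 in strips. Reads of X-linked paralogs are argued against, since the 4 Y-linked genes fell together in replicate 2, with medians that spanned 0.25 on the log2 scale. Whether same-numbered samples share a pool of male and female animals stays open. The ratio differed between the numbers as much in 3 of all possible numberings (exact one-sided permutation p = 0.014), but those are the values in which the pattern was seen. The labels do not give the sex of the animals, and no biological explanation was tested.

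Strips replicate 2 held the most RNA of intestinal epithelium. All 15 enterocyte genes were highest there, with a median log2 ratio of 3.33 to the other strips, among them Apoa4 at 2330 CPM against 127 and 234, and Fabp1 at 98.2 against 6.41 and 8.89. A larger share of the same mix of epithelial cells would raise goblet cell and colonocyte genes by a like ratio. The 10 such genes had a median ratio of 1.34, with an SD of 1.06. That lay below the enterocyte median by more than the SD of either list, which by the rule of this test goes against the same mix. These genes cannot settle it, since their ratios overlap those of the enterocyte genes. Among them Mgst1, at 0.155, is not particular to epithelium, with 174 to 287 CPM in P plate and 59.2 to 73.9 in strips. The 10 ratios ranged from -0.489 for Agr2 to 2.78 for Clca1, and those of the enterocyte genes from 2.54 to 3.76. Villous enterocytes carried over with the muscle may also account for the pattern, since their 15 log2 ratios had an SD of 0.409. No biological explanation was tested.

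For each comparison 10 splits of its 6 libraries into groups of 3 were counted, too few for a share under 0.05. The real groups called 4400 genes in M plate against P plate and 562 in M scaffold against M plate, with 0 as the highest of the other splits in both. Against strips they called 11175 in P plate, 9712 in M plate and 9228 in M scaffold, with 1, 0 and 0 as the highest of the other splits. In each comparison the number of splits with a result as large was 1, the real one.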
